A study of Mus musculus with 4 samples.

How the data were processed

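The study comprises 4 samples, an H3K27me3 immunoprecipitation and an input of lineage-negative progenitors from adult bone marrow and the same pair from fetal liver, all transduced with NOTCH1ΔE. Each of the 2 immunoprecipitation samples came with 1 list of broad peaks. The 2 inputs entered as the control of the peak calls and were not analysed here on their own. Groups were taken from the sample titles, with 1 sample in each.

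Per the submitters' processing notes, BWA 0.5.7, Picard and MACS2 2.1.0 were used with the mouse build mm9. The settings, the filters and the read numbers are not given in the sources used here. Peak names in the deposited lists say that merged libraries were compared with input, and the number of libraries merged is not given in the sources used here. Values were averaged over a peak by the caller in this file format, so a wide peak can have a modest mean while a short one keeps its local maximum. The fold enrichment column of the deposited lists is the authors' ratio of immunoprecipitation to input. The 2 significance columns deposited by the authors are −log10 p and −log10 q per peak. The deposited score column is 10 times the −log10 q without its decimals, in all but 1 peak of each list, and was not used further. Fold and significance were used to describe, rank or filter the peaks of each list. The same cuts were applied to both lists, and some medians are set side by side. Whether the 2 scales are comparable between lists of unknown depth was not tested. The depth of the libraries is unknown, and a deeper library gives more and wider peaks at a fixed threshold, so the length of a list is not a measure of the amount of the mark. Peaks were called once per cell type, so the error between cultures or animals cannot be estimated and no p-value between cell types is given.

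No peak reached past an mm9 chromosome end, with chromosome lengths from GenomeInfoDb 1.38.1. Both lists held peaks on chromosomes 1 to 19 and X and none on Y, and no peaks of a list overlapped each other. Coordinates are given from 1. Overlap was counted from 1 bp. The bases in common and the peaks hit were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 and checked against bedtools 2.31.1, with identical counts. The same code was tested on simulated data with known shared and private intervals of the real widths, and the total of each class was recovered over 3325 simulated regions. Classes were not compared region by region. The simulated regions lay too far apart to test the joining of neighbouring peaks. Chance overlap was described with 100 circular shifts of the fetal liver peaks, 1 random shift for each chromosome, leaving out the first 3 Mb. Union regions were made by joining peaks of either list at most 3 kb apart. A region was assigned to a single population when it held no peak base of the other list. Shares of peaks have 95% Wilson intervals from scipy 1.17.1, and ratios of peak numbers have intervals from the same method on the share of fetal liver peaks. Neighbouring peaks are not independent, so these intervals are too narrow as a measure of biological error. Figures were drawn with matplotlib 3.10.9.

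The comparisons, the rule for named regions (the 5 widest of each class) and most alternatives were fixed before the data were examined. The alternatives were a −log10 q of at least 5, a fold enrichment of at least 3, a fetal liver list reduced to the number of bone marrow peaks by −log10 p, autosomes only, peaks of at least 1 kb, other overlap rules and other joining distances. A −log10 q of at least 2 and a fetal liver list reduced to the covered length of the bone marrow list were added after seeing the data. Promoter coverage, the gene lists and the named genes had also been planned. The only gene table at hand was on GRCm38, another build than that of the peaks, so no gene was placed on the peaks and gene-level results are not analysed here.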

Results

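Trimethylation of histone H3 at lysine 27 (H3K27me3), a mark laid down by Polycomb repressive complex 2 and found over silenced developmental loci, was mapped in mouse blood progenitors of fetal and adult origin. The progenitors were lineage-negative cells, which lack the surface markers of mature blood cells. They came from the bone marrow of 8-week-old C57BL/6 mice or from fetal livers at embryonic day 14.5, where blood formation takes place before it moves to the marrow. Both populations carried a lentivirus encoding NOTCH1ΔE (N1dE), a form of NOTCH1 cut short on its extracellular side that drives T-cell leukaemia, and were sorted by the GFP marker after 3 days in culture. Native chromatin immunoprecipitation on micrococcal nuclease-digested chromatin was followed by sequencing. The comparison asks where the H3K27me3 landscape of NOTCH1-transduced progenitors depends on their developmental source. There was 1 peak list for each cell type, called by the authors on merged immunoprecipitation libraries against input. No spread between replicates can be had from them, so no test between the cell types was made and the values below describe these 2 lists. The read depth behind them is unknown, and intervals cover counting error over peaks only.

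H3K27me3 peaks as deposited were more numerous and covered more of the genome in fetal liver than in bone marrow progenitors, but not among peaks above the cuts on −log10 q or fold enrichment. The fetal liver list held 31847 peaks over 60.8 Mb, or 2.30% of the mm9 chromosomes 1 to 19 and X, and the bone marrow list held 20024 peaks over 40.4 Mb, or 1.53%. The ratio of peak numbers was 1.59 (95% Wilson interval 1.56 to 1.62) and that of covered length was 1.51. With the fetal liver list reduced to its 20024 highest-ranked peaks, the ratio of covered length was 1.09. Most peaks in both populations were short. The median width was 945 bp in fetal liver and 957 bp in bone marrow, and only 8.02% and 9.54% of peaks, respectively, reached 5 kb. These wide peaks nevertheless held 39.9% of the covered length in fetal liver and 42.6% in bone marrow. They numbered 2553 in fetal liver and 1910 in bone marrow, a ratio of 1.34 (1.26 to 1.42). Fold enrichment over input, as the authors' peak caller gave it, had a median of 1.93 (interquartile range 1.71 to 2.23) in the fetal liver list and 2.12 (1.86 to 2.47) in the bone marrow list. The median −log10 q was 1.09 in the fetal liver list and 1.38 in the bone marrow list. The excess of fetal liver peaks turned around among peaks with a high score: 302 bone marrow and 168 fetal liver peaks had a −log10 q of at least 5, and 1766 and 1446, respectively, had a fold enrichment of at least 3. At a −log10 q of at least 2 there were 5313 bone marrow and 4844 fetal liver peaks, so most peaks of each list lay below this cut. Whether a given score means the same in 2 lists of unknown depth was not tested.

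In the lists as deposited, every autosome was covered more in fetal liver, whereas the X chromosome was covered more in bone marrow. Among the 19 autosomes the ratio of peak numbers, fetal liver over bone marrow, ran from 1.44 on chromosome 19 to 1.89 on chromosome 14, with a median of 1.60. On the X chromosome the ratio was 0.613 (95% Wilson interval 0.532 to 0.706), with 312 peaks in fetal liver and 509 in bone marrow. The covered length followed the same order, with 387.0 kb of X in fetal liver peaks and 562.4 kb in bone marrow peaks. Chromosome 11 was the most densely covered in both lists, with 4.46% of its length in fetal liver peaks and 2.88% in bone marrow peaks. X was the least densely covered in both, at 0.232% and 0.337%. The fullest 1 Mb window of X, from 100 to 101 Mb, was the same in both populations and held 49 bone marrow and 24 fetal liver peaks. The window from 91 to 92 Mb held 26 and 3. The labels do not give the sex of the animals. The ratio on X was 0.379 times that of all autosomes together. It was 0.50 times among peaks of at least 1 kb, 0.358 times after joining peaks of a list within 3 kb, 0.324 times at a fold enrichment of at least 3 and 0.273 times at a −log10 q of at least 2. With the fetal liver list alone reduced to the number of bone marrow peaks or to their covered length it was 0.245 and 0.224 times. X peaks ranked low by −log10 p in the fetal liver list, at a median percentile of 29.6. Cutting that list alone can therefore lower the value by itself, and these 2 settings are no further support. The X ratio itself ran from 0.210 to 0.792 over these settings.

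**Figure D1:**
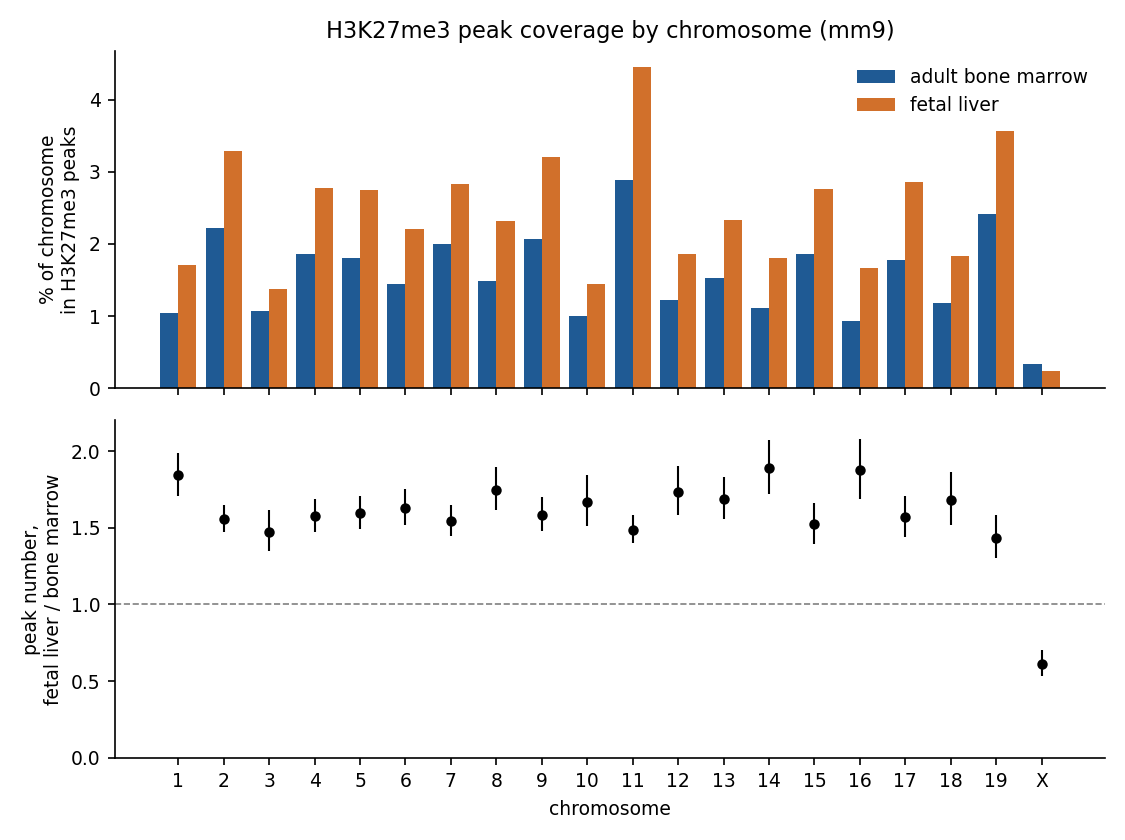
Upper panel: percentage of each mm9 chromosome inside H3K27me3 peaks in adult bone marrow (blue) and fetal liver (orange) progenitors; lower panel: ratio of peak numbers per chromosome with its 95% Wilson interval, and a dashed line at equality. All 19 autosomes lie between 1.44 and 1.89, and X lies at 0.613.

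**Figure D2:**
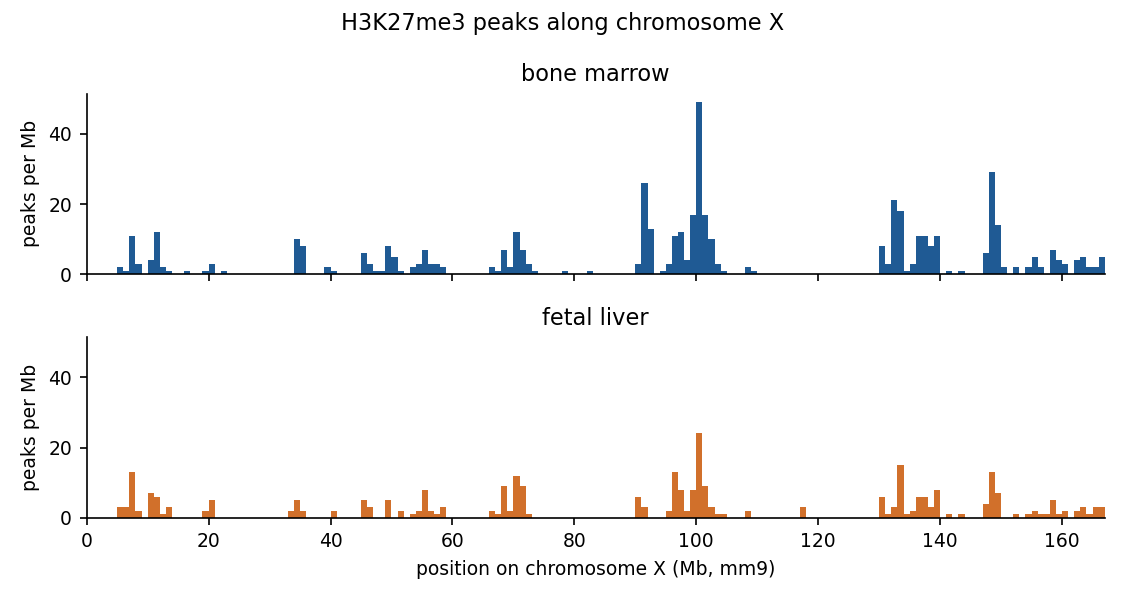
Number of H3K27me3 peaks in each 1 Mb window of chromosome X (mm9) in bone marrow (blue, upper) and fetal liver (orange, lower). The window from 100 to 101 Mb holds the most peaks in both, 49 and 24.

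The same regions carried the mark in both populations far more often than random placement gave. Of the bone marrow peaks, 13619 (68.0%, 95% Wilson interval 67.4 to 68.7%) overlapped a fetal liver peak by at least 1 bp. When the fetal liver peaks were moved along each chromosome by random circular shifts, the share was 4.75% on average over 100 shifts, with a range of 3.93 to 5.52%. The shifts did not keep peaks within any class of sequence, so they cannot show why the lists overlap. Of the fetal liver peaks, 12667 (39.8%, 39.2 to 40.3%) overlapped a bone marrow peak, against 3.07% after shifting. In bases, 29.9 Mb lay in both lists, 10.5 Mb in the bone marrow list alone and 30.9 Mb in the fetal liver list alone. The bases in common were 74.1% of the bone marrow and 49.2% of the fetal liver coverage, and the Jaccard index was 42.0%, against 1.08% after shifting. These shares depended on the score and the length of the lists. With the fetal liver list reduced to the number of bone marrow peaks they were 47.9% of bone marrow and 42.4% of fetal liver peaks. With both lists limited to a −log10 q of at least 2 they were 9.67% and 10.4%, to a fold enrichment of at least 3 they were 1.19% and 1.31%, and to a −log10 q of at least 5 they were 0%. Such cuts leave fewer peaks to be hit, and no chance level was set for the cut lists. Low shares there do not by themselves show that high-scoring sites belong to a single population. On X, where the bone marrow list was the longer, 32.2% (28.3 to 36.4%) of bone marrow and 56.1% (50.5 to 61.5%) of fetal liver peaks had an overlap; no chance level was set for X alone.

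Nearly all peaks of 5 kb or more overlapped a peak of the other list, and the peaks without an overlap were mostly short. A wider peak is more easily hit by at least 1 bp, and no chance level was set by width. Among bone marrow peaks of at least 10 kb, 452 of 454 overlapped a fetal liver peak, and among fetal liver peaks of that width 674 of 676 overlapped a bone marrow peak. In the class of 5 kb to under 10 kb the shares were 99.7% of bone marrow and 97.6% of fetal liver peaks. In the class from 0.2 kb to under 0.5 kb they were 43.7% and 15.6%. Rank by −log10 p within a list gave no steady rise. With each list split into 10 rank classes of equal size, the overlapping share was 51.7% in the lowest class of bone marrow peaks, 74.5% in the fifth and 60.8% in the highest. In fetal liver it was 21.4%, 45.5% and 28.7% in the same classes. Width differed between these classes in the same order, with medians of 647, 1324.5 and 769 bp in bone marrow and 638, 1202 and 773 bp in fetal liver, so rank was not separated from width here. Among peaks with a −log10 q of at least 5, 0 of 302 bone marrow peaks overlapped one of the 168 such fetal liver peaks. With 3 peaks taken as the upper bound for a count of 0, which is not a Wilson interval, this allows a share of up to 0.993%. Only 168 of the 31847 fetal liver peaks could be hit here, and no chance level was set for so short a list. Against the whole other list, 168 of these 302 bone marrow peaks (55.6%) and 29 of the 168 fetal liver peaks (17.3%) had an overlap.

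**Figure D3:**
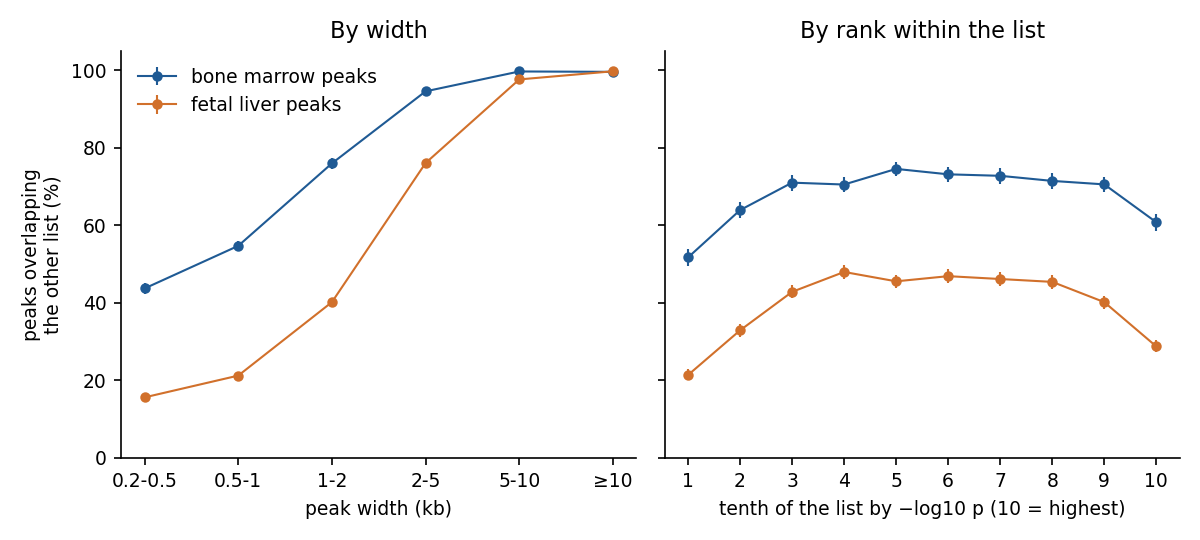
Percentage of peaks that overlap the other list by at least 1 bp, with 95% Wilson intervals, for bone marrow (blue) and fetal liver (orange) peaks, against peak width in kb (left) and against 10 rank classes of the list by −log10 p (right, 10 the highest). The share is higher in wide than in short peaks, at 99.6% and 99.7% at 10 kb and above, and is lower in the highest rank class, at 60.8% and 28.7%, than in the fifth.

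Joining peaks of either list that lay within 3 kb gave 22283 regions, of which 9277 (41.6%) were marked in both populations, 10118 (45.4%) in fetal liver only and 2888 (13.0%) in bone marrow only. The shared regions were broad, with a median width of 5157 bp, and held 38.0 of the 40.4 Mb covered in bone marrow and 50.3 of the 60.8 Mb covered in fetal liver. Within 6409 of them (69.1%) the fetal liver peaks covered more bases than the bone marrow peaks. The regions of a single population were short, with a median of 644 bp for bone marrow only and 776 bp for fetal liver only. Part of this contrast follows from the definition, since a shared region holds a peak of each list and a wider region more easily holds both. At a width of 5 kb or more there were 38 bone-marrow-only and 418 fetal-liver-only regions. On the autosomes fetal-liver-only regions outnumbered bone-marrow-only regions by 10049 to 2635, and on X the order was the opposite, 69 to 253. When the fetal liver list was reduced to its 20024 highest-ranked peaks, the numbers moved to 6680 fetal-liver-only and 5485 bone-marrow-only regions. Under the cuts on score the order turned around, with 160 fetal-liver-only and 281 bone-marrow-only regions at a −log10 q of at least 5, 1287 and 1572 at a fold enrichment of at least 3, and 3349 and 3672 at a −log10 q of at least 2.

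The widest domain marked in bone marrow and free of fetal liver peaks was on chromosome 11, from 95850268 to 95892554 (mm9). Its 4 bone marrow peaks covered 37.1 kb, or 87.7% of the region, and the widest of them spanned 20.6 kb with a fold enrichment of 2.27 and a −log10 q of 1.97. The closest fetal liver peak lay 45.3 kb away. It was 2.5 times as wide as the next bone-marrow-only region, which was on chromosome 6 from 49160667 to 49177491, with 14.8 kb in 3 bone marrow peaks and a fetal liver peak 8.91 kb away. The others were on chromosome 3 from 106006170 to 106022509, with 9.40 kb in bone marrow peaks, on chromosome 3 from 52141421 to 52156002, with 4.75 kb, and on chromosome 6 from 48684908 to 48697657, with 6.26 kb. The first of these was the most isolated, since the closest fetal liver peak was 496.4 kb away.

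The widest region marked in fetal liver and free of bone marrow peaks was on chromosome 17, from 34536953 to 34563928, where 7 fetal liver peaks covered 16.2 kb. On chromosome 4, from 129752608 to 129778071, 6 fetal liver peaks covered 16.8 kb, and the closest bone marrow peak was 26.6 kb away. The remaining regions were on chromosome 13 from 55969798 to 55992074, with 12.9 kb in fetal liver peaks, on chromosome 2 from 93755497 to 93774561, with 6.85 kb, and on chromosome 15 from 85489867 to 85508558, with 12.7 kb. The closest bone marrow peak was 32.2 kb from the chromosome 17 region and 30.0 kb from the chromosome 15 region. It was only 6.37 kb from the chromosome 13 region and 4.24 kb from the chromosome 2 region, which joining within 10 kb would make shared. In each of these 5 regions the widest single peak was 6.55 kb or shorter. Its −log10 q was 0.86 to 1.63, against 1.14 to 2.03 for the widest peaks of the 5 bone-marrow-only regions. The chromosome 3 regions and the last chromosome 6 region of bone marrow held no peak above 3.29 kb.

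The widest shared domains were filled for 85.0 to 95.3% by fetal liver peaks and for 62.5 to 92.5% by bone marrow peaks. On chromosome 15, from 102708470 to 102981005, a region of 272.5 kb was covered for 229.8 kb in bone marrow and 255.2 kb in fetal liver. It held the widest single peak of each list, of 135.1 kb in bone marrow and 169.2 kb in fetal liver. On chromosome 2, from 74477491 to 74611548, coverage was 124.0 kb in bone marrow and 127.7 kb in fetal liver. On chromosome 11, from 95995956 to 96245526, it was 156.1 kb and 219.5 kb, and this domain began 103.4 kb beyond the end of the widest bone-marrow-only region. On chromosome 6, from 52093230 to 52279715, bone marrow peaks covered 122.0 kb and fetal liver peaks 158.6 kb. On chromosome 11, from 61320699 to 61454228, they covered 83.5 kb and 114.8 kb.

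**Figure D4:**
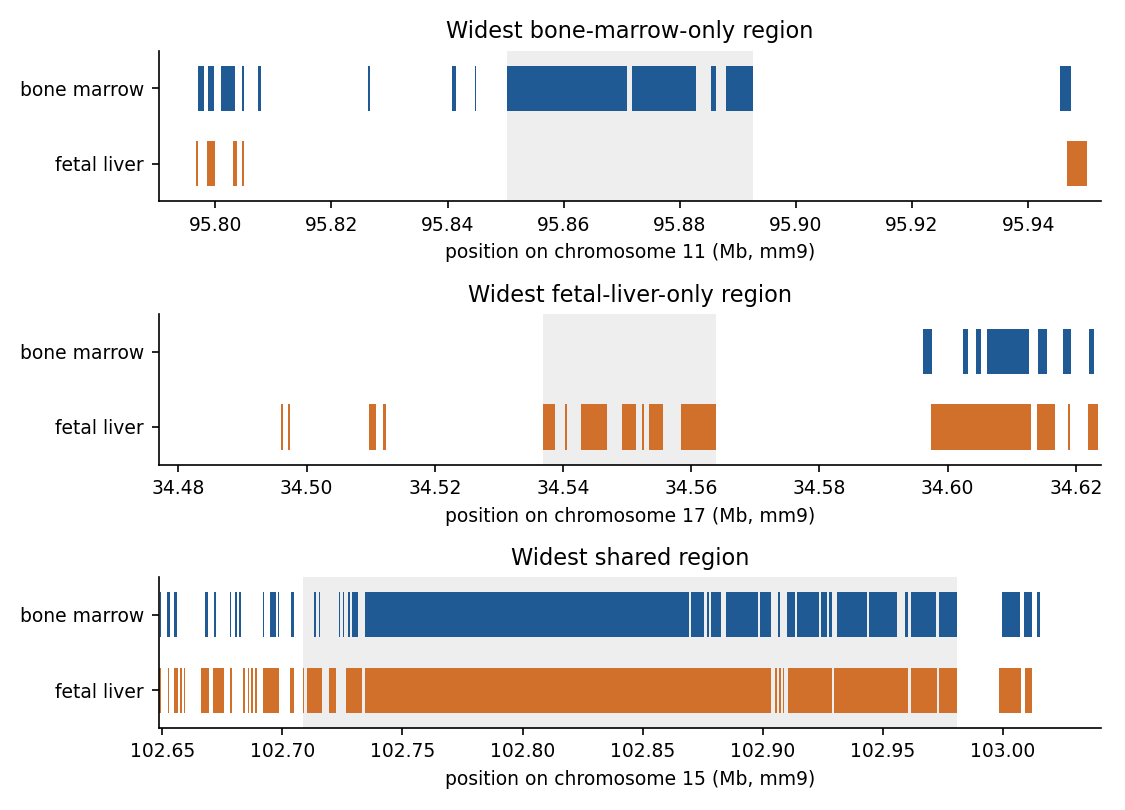
Peaks of the bone marrow (blue) and fetal liver (orange) lists along the widest bone-marrow-only, fetal-liver-only and shared regions, which are shaded, with flanks on each side; the horizontal axes give mm9 positions in Mb. Bone marrow peaks fill 87.7% of the chromosome 11 region with no fetal liver peak in it, 7 fetal liver peaks cover 16.2 kb of the chromosome 17 region, and both lists fill most of the chromosome 15 region.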

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

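No paired analysis was possible because there is 1 peak list per cell type. The planned promoter and gene list results were not run, since no gene positions on mm9 were used here. A cut on −log10 q of at least 5 turned the ratio of peak numbers (fetal liver over bone marrow) to 0.556 and that of covered length to 0.523, left 0% of either list overlapping, and left 281 bone-marrow-only and 160 fetal-liver-only regions; no X ratio could be formed there. A fold enrichment of at least 3 gave 0.819 and 0.674, overlaps of 1.19% of bone marrow and 1.31% of fetal liver peaks, 1572 and 1287 regions, and an X ratio of 0.267 from 15 bone marrow and 4 fetal liver peaks. A −log10 q of at least 2, added after seeing the data, gave 0.912 and 0.692, overlaps of 9.67% and 10.4%, 3672 bone-marrow-only and 3349 fetal-liver-only regions, and an X ratio of 0.25. The median widths of bone marrow and fetal liver peaks after these 3 cuts were 672.5 and 624.5 bp, 707 and 670 bp, and 929 and 835 bp, and the cause of the turn was not tested. With the fetal liver list reduced to the number of bone marrow peaks, the ratio of covered length was 1.09, against 1.51 as reported. Overlaps were then 47.9% and 42.4%, there were 5485 bone-marrow-only and 6680 fetal-liver-only regions, and the X ratio was 0.250. Reduced to the covered length of the bone marrow list, also added later, the fetal liver list held 0.922 times as many peaks, with overlaps of 43.8% and 42.0%, 6004 and 6254 regions, and an X ratio of 0.210. Peaks of at least 1 kb gave overlaps of 77.9% and 48.4%, 1387 and 5062 regions, and an X ratio of 0.792. Autosomes alone gave an overlap of 68.9% of bone marrow peaks. Joining peaks of a list within 3 kb gave a ratio of peak numbers of 1.48. Requiring cover of 50% of a peak gave overlaps of 55.3% and 26.4%, a 50% reciprocal overlap 28.3% and 17.8%, and allowing a distance of 3 kb 83.1% and 56.4%. Regions joined only where they touched numbered 6405 for bone marrow only and 19179 for fetal liver only, regions joined within 10 kb 1629 and 5229, and regions of at least 5 kb 38 and 418. Of 77 alternative values 20 stayed within the 95% interval of the reported value or, for values without one, within 1.5 times of it, and 7 turned the direction of a ratio. The X ratio can only fall where the fetal liver list alone is reduced, and the score cuts put the autosomes below 1 too. Divided by the ratio of the autosomes under the same setting, a comparison added after seeing the data, it was 0.379 as reported, 0.50 for peaks of at least 1 kb, 0.358 after joining, 0.324 at a fold enrichment of at least 3 and 0.273 at a −log10 q of at least 2. The unknown read depth limits every comparison of list length.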

Other observations

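The tests below, other than those of the top 10% of fetal liver peaks, of the rank and clustering of X peaks and of nearby fetal liver peaks, were chosen after the result was seen. Joining peaks of a list within 3 kb had been planned as an alternative, but its use as a test of splitting was chosen later. Over 1978 autosomal windows of 1 Mb with a peak in either list, the covered lengths had a Spearman correlation of 0.94 across windows, which are not replicates, and over 86 windows of X it was 0.77. The fullest window in both lists was chromosome 15 from 102 to 103 Mb, with 326.8 kb in bone marrow and 379.8 kb in fetal liver peaks, followed by chromosome 11 from 96 to 97 Mb, with 240.1 kb and 327.8 kb. Bone marrow covered more than fetal liver in 323 autosomal windows and less in 1655. The largest excess of bone marrow was on chromosome 3 from 96 to 97 Mb, with 168.9 kb against 135.9 kb, and the largest excess of fetal liver on chromosome 2 from 164 to 165 Mb, with 272.4 kb against 125.3 kb. On X, bone marrow covered more in 65 of the 86 windows.

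Several shared domains were filled unequally; they were picked by the size of the difference. A shared region on chromosome 4, from 129633844 to 129720137, lay before the fetal-liver-only region described above and was not joined to it. Fetal liver peaks covered 64.1 kb of this shared region and bone marrow peaks 20.5 kb. On chromosome 17, from 36262471 to 36381756, they covered 105.6 kb and 64.4 kb. In the other direction, chromosome 3 from 96221347 to 96282340 was covered for 51.5 kb in bone marrow and 34.9 kb in fetal liver, and chromosome 2 from 17944654 to 17975467 for 23.5 kb and 12.6 kb. The 3 highest-ranked peaks of each list with no peak of the other list within 3 kb were 294 to 1866 bp wide in bone marrow and 621 to 1226 bp wide in fetal liver. In bone marrow the first was on chromosome 2 from 153841451 to 153841796 (346 bp, fold enrichment 6.84), and in fetal liver on chromosome 9 from 121070586 to 121071484 (899 bp, fold enrichment 6.36).

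The longer fetal liver list on every autosome could come from unequal depth, from the way peaks were split, or from the source of the cells. Splitting is not the whole cause, since joining peaks of a list within 3 kb took the ratio of peak numbers from 1.59 to only 1.48 (95% Wilson interval 1.45 to 1.51), and splitting would not add covered length. Short calls of a single library are not the whole cause either, since peaks of at least 5 kb were 1.34 times as many in fetal liver (2553 against 1910). Most of the excess in number was nevertheless in shorter peaks, with 31847 against 20024 peaks of all widths. Lower depth or sensitivity in bone marrow cannot be told apart from a difference between adult and fetal cells. Only 28.7% of the top 10% of fetal liver peaks overlapped a bone marrow peak, where a depth effect alone was predicted to leave 95% or more. However, the top 10% of bone marrow peaks was itself overlapped in only 60.8% by the longer list. The prediction assumed that rank orders peaks by how easily they are called, which was not tested, so it cannot decide. The source of the cells stays open and untested, with 1 list each.

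The X chromosome had fewer peaks in fetal liver, with a ratio of 0.613. Lower sensitivity in bone marrow would act in the other direction, leaving fewer bone marrow peaks on X too, whereas the lowest ratio of an autosome was 1.44. This follows from the direction of the difference alone and does not bear on other technical causes, which were not tested. X peaks in the bone marrow list ranked low by −log10 p, with a median percentile of 24.3, above the 10 predicted for calls at the threshold and just under the 25 set against it, and X peaks of fetal liver ranked low too, at 29.6. The lower ratio on X was not limited to low-scoring calls. At a −log10 q of at least 2 there were 40 bone marrow and 10 fetal liver peaks on X. This ratio was 0.25 (95% Wilson interval 0.127 to 0.493), against 0.917 on the autosomes. Because X peaks ranked low in both lists, a fixed cut may act more strongly on X than on the autosomes. Marginal calls are therefore not excluded as a cause. A hypothesis is that more of the bone marrow cells had a second, silenced X with diffuse H3K27me3; of the 345 bone marrow X peaks without a fetal liver peak, the 10 fullest of 72 windows held 48.1%, between the 20% predicted for a diffuse signal and the 50% set against it, and the labels give no sex.

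The highest-ranked peaks of each list were often absent from the other: 786 of the 2003 bone marrow peaks in the top 10% had no overlapping fetal liver peak. Calls missed beside a called peak could account for part: 47.1% of the 786 had a fetal liver peak within 3 kb, which neither reaches the 80% predicted nor falls under 20%. Of the 3185 fetal liver peaks in the top 10%, 2270 had no overlapping bone marrow peak, and 27.9% of these had one within 3 kb. Absence was also common in the whole lists, where 68.0% of bone marrow and 39.8% of fetal liver peaks overlapped, against 60.8% and 28.7% in the top 10%. With peaks within 3 kb counted, the shares were 83.1% and 56.4%, against 79.2% and 48.6%. Nearness was thus not shown to be a trait of the top 10%, and no chance level was set for 3 kb. By width, 93.4% of the bone marrow peaks in the top 10% with at least 2 kb overlapped a fetal liver peak, against 48.3% of those under 1 kb, but the whole list split in the same way, with 96.3% and 49.6% (fetal liver 73.4% and 16.8% in the top 10%, 83.0% and 18.7% in the whole list), so this does not show what a high mean −log10 p marks. Whether the short private peaks are noise of a library or sites of a single cell type stays open, since each cell type has 1 list.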
